A study of Mus musculus with 12 samples.

How the data were processed

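The 12 libraries fall into Tet2 knockout and double knockout groups by their titles, with 2 libraries per genotype for RNA-seq and bisulfite sequencing and 1 per genotype for CMS and H3K27me3. Per the labels, each library is a technical replicate of a biological replicate, and each CMS library joins 2 technical replicates. Coordinates are mm9, per the submitters' processing notes, and are given 1-based.

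The RNA values are FPKM as deposited, 1 per RefSeq transcript, from reads aligned with TopHat2 2.0.10 per the submitters' processing notes; the program that made the FPKM and the filter on transcripts are not stated. The bisulfite files hold deposited counts of all reads and of methylated reads at each CpG, with both strands summed, and the methylated fraction per CpG per the file headers, from BSMAP 2.87 alignments per the submitters' processing notes. The CMS and H3K27me3 lists hold the score of each peak as deposited, whose kind is not stated, from MACS2 after BSMAP 2.87 (CMS) or Bowtie2 2.2.7 (H3K27me3), per the submitters' processing notes. The CMS lists and the double knockout H3K27me3 list hold 1 bp summits; the Tet2 knockout H3K27me3 list holds intervals of median length 349.5 bp.

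The tests, their thresholds, the gene lists and most alternatives were fixed before the data were examined. RNA was tested with limma 3.58.1 (trend and robust; R 4.3.3, statmod 1.5.0) on log2(FPKM + 1) over transcripts listed in all 4 libraries with an FPKM above 1 in at least 2; p-values were adjusted by Benjamini-Hochberg and called under 0.05. Gene lists with at least 3 tested members went through camera (preset correlation, and estimated correlation) and fry. Named genes are, by rule, Tet2 and Dnmt3a, Klf1, Epor, Gata1, Dnmt1, Dnmt3b, Tet1 and Tet3, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap (leaving out predicted-gene symbols), and up to 4 called members per list. Named tiles are the 5 largest falls and 5 largest rises, named regions the 5 widest undermethylated regions, and named peaks come from the 3 highest-scoring shared ones per list; others are stated in the text as chosen after their values were seen.

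The methylation level per library is methylated over all reads at autosomal CpG sites; the mean over sites with at least 5 reads stands beside it. About 2000 sites per library had over 100 reads and held 30.5% to 31.6% of all reads, so values by chromosome, CpG density, undermethylated region and peak leave them out. Genotype means were compared with two-sided exact permutation tests over libraries (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). Tiles of 1000 bp with at least 3 sites of at least 5 reads in every library were tested with edgeR 4.0.16, by its quasi-likelihood test on methylated and unmethylated counts with an intercept per library and a dispersion from 20000 seeded tiles; a call needs an adjusted p under 0.05 and a difference of at least 20 points. Median reads per tile were 118 over the 4 libraries.

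Undermethylated regions are runs of at least 5 autosomal sites and 1000 bp at or below 10%, smoothed over 5 sites, with gaps of at most 1000 bp and at least 5 pooled reads per site. For widths and numbers by genotype or library, reads were thinned to the depth of the shallowest library, with at least 3 reads per site for 2 libraries and 1 for single libraries. CMS summits count as shared within 1000 bp of each other, since 1 bp summits seldom overlap; H3K27me3 peaks count as shared where a summit lies in an interval. Shuffled shares come from 100 placements within chromosomes (20 for undermethylated regions). Methylation was read in intervals, and within 500 bp of 1 bp summits. Intervals on shares cover counting error only.

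How far replicates are independent was checked by comparing libraries over 2000 bp tiles. The mean chi-square was 2.33 to 2.59 between the strands of each library, 2.38 and 2.54 between replicates, and 3.10 to 3.60 between genotypes. Replicates thus differed about as much as the strands of a library, and p-values here measure the spread between these libraries, which may hold little variation between animals.

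The RNA test, the tile test and the region calls were tested on simulated data. For RNA, 67.1% of changes of log2 size 1 and 94% of size 2 were recovered among 399 transcripts. For tiles, the simulation first lowered 2000 of 39381 tiles above 50% methylation, and recovered 0.1% of falls of 20 points and 1% of falls of 30 points; a later simulation from tiles above 85% recovered 9.2%, 45.4%, 84.4% and 99% of falls of 20, 40, 60 and 80 points. Falls of 20 and 30 points in single tiles were therefore mostly missed in these simulations. Recovery there needed an adjusted p under 0.05, without the minimum difference of 20 points. The simulations added a fixed spread between libraries, not estimated from these data, and used only the depth of these data. How many falls were missed in the real tiles is therefore not known. They do not separate depth from that spread as a cause of the low recovery. For undermethylated regions, 82.2% of planted regions were found, 100% of those of at least 3500 bp, and none outside them.

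Gene names of regions come only from the transcript spans in the RNA files, which carry no strand, so promoters were not analysed here and neighbours are the nearest listed transcripts. The planned edgeR test of RNA needs counts and was replaced by the limma test fixed for normalized values. Tests alternative to these, other filters, pseudocounts, scalings, tile sizes, levels, sharing distances, each replicate left out and the replicate number as a block were tried. Figures were drawn with matplotlib 3.10.9.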

Results

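The data describe mouse haematopoietic stem cells (HSCs; lineage-negative, cKit+, Sca1+, CD48-, CD150+) taken from secondary transplant recipients. The donor marrow lacked either Tet2, an enzyme that oxidises 5-methylcytosine to 5-hydroxymethylcytosine, or both Tet2 and the DNA methyltransferase Dnmt3a. The 12 libraries hold RNA-seq (2 Tet2 knockout, 2 double knockout), whole-genome bisulfite sequencing (2 and 2), CMS pull-down (1 and 1) and H3K27me3 ChIP-seq (1 and 1). CMS, cytosine 5-methylenesulfonate, is what bisulfite makes of 5-hydroxymethylcytosine. H3K27me3 is the repressive mark set by Polycomb. Every comparison sets the double knockout against the Tet2 knockout and asks what loss of Dnmt3a adds to loss of Tet2 in these cells.

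The bisulfite files listed 19702332 and 17043181 CpG sites in Tet2 knockout replicates 1 and 2, and 18701530 and 18133484 in double knockout replicates 1 and 2. Mean reads per CpG site were 4.33, 2.45, 3.75 and 3.21 in the same order, so single sites are poorly measured and regions carry the comparisons. The RNA files listed 10482, 9984, 10788 and 10604 transcripts with an FPKM each and give no read depth. Tet2 and Dnmt3a were not listed in any RNA library, so the deleted genes could not be used to check the labels. Epor, Gata1, Dnmt1, Dnmt3b, Tet1 and Tet3 were not listed either. Klf1, an erythroid transcription factor, was listed only in the Tet2 knockout, at 25.2 and 10.7 FPKM, and was not compared. Its absence from the double knockout lists does not show low expression, since highly expressed transcripts are missing from some libraries too. Rplp1, for example, was listed only in double knockout replicate 1, at 2910 FPKM.

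CpG methylation was lower in the double knockout across the genome. Summed over autosomal reads, the level was 83.4% ± 0.317 (SD, n = 2) in the Tet2 knockout and 78.2% ± 0.00421 (SD, n = 2) in the double knockout, a difference of -5.15 percentage points. All 19 autosomes were lower, with both double knockout libraries below both Tet2 knockout libraries on each; the differences ran from -5.69 points on chromosome 12 to -7.95 points on chromosome 11, at sites of at most 100 reads. In percentage points, DNA of intermediate CpG density lost most. The difference was -7.03 points at sites with 11 to 20 CpG sites within 500 bp (86.9% against 79.8%), -4.60 points at sites with 1 to 5, and -2.29 points at sites with 41 or more, where the Tet2 knockout level was 17.4%. Averaged over sites with at least 5 reads, the level was 80.9% ± 0.307 against 73.6% ± 0.154 (SD, n = 2 each), a difference of -7.27 points. The size depends on the sites taken: with at least 10 reads per site it was -3.19 points for summed reads and -8.03 for the mean over sites. Each difference exceeded the spread between replicates, but the two-sided exact permutation p was 0.333, the smallest that 2 against 2 libraries allow.

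The loss was steepest beside DNA that was already unmethylated. Undermethylated regions are runs of CpG sites at or below 10% methylation, and those of at least 3500 bp are called canyons. Reads pooled over the 4 libraries gave 9031 such regions on the autosomes, of which 235 were canyons. In their 1000 bp flanks the level was 47.1% ± 0.366 in the Tet2 knockout and 31.3% ± 0.0251 in the double knockout (SD, n = 2 each), a difference of -15.8 points; beside canyons it was 43.8% ± 0.863 against 24.5% ± 0.217, a difference of -19.3 points. At 4000 to 5000 bp away the differences were -10.4 and -14.7 points. Inside the regions the levels were 0.865% and 0.571%. Of the 8958 regions with enough flanking reads, 90.1% had lower flanks in the double knockout. The exact permutation p over libraries was 0.333 for each, the smallest possible.

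**Figure D1:**
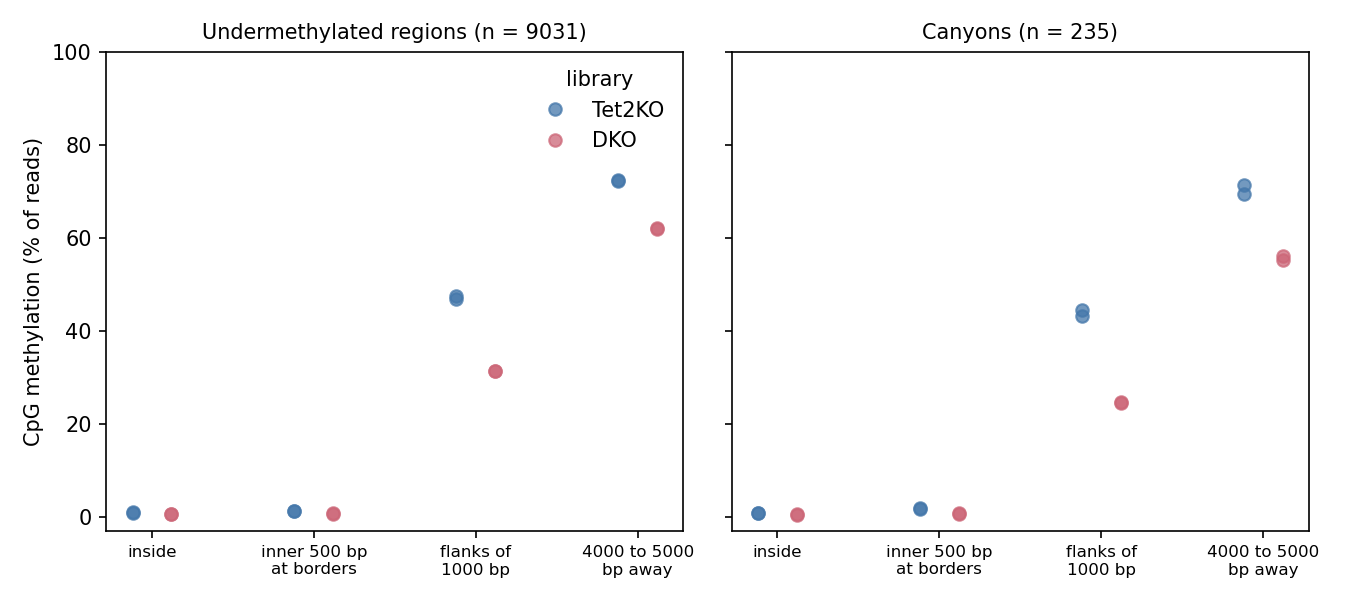
CpG methylation (percent of reads) inside undermethylated regions, at their inner borders, in their 1000 bp flanks and 4000 to 5000 bp away. Each point is 1 library, with 2 per genotype; in canyon flanks the Tet2 knockout libraries sit at 44.4% and 43.2% and the double knockout libraries at 24.4% and 24.7%.

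Canyons were wider and more numerous in the double knockout. With reads thinned to the same depth, the Tet2 knockout had 178 canyons and the double knockout 378. Called in single libraries, the numbers were 152 and 168 against 373 and 352. Of the 235 pooled canyons, 179 were wider in the double knockout and 56 narrower, with a median change of 539 bp. In 126 canyons both double knockout libraries were wider than both Tet2 knockout libraries, and in 6 both were narrower, where chance gives 16.7% each way. Canyons come from the same 4 libraries and are not independent replicates. Mean widths were 4003 and 3966 bp in the Tet2 knockout libraries and 4846 and 4898 bp in the double knockout libraries. The exact permutation p over libraries was 0.333, the smallest possible. A called region counts in full for each pooled canyon it overlaps, so neighbouring canyons can share the same width.

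**Figure D2:**
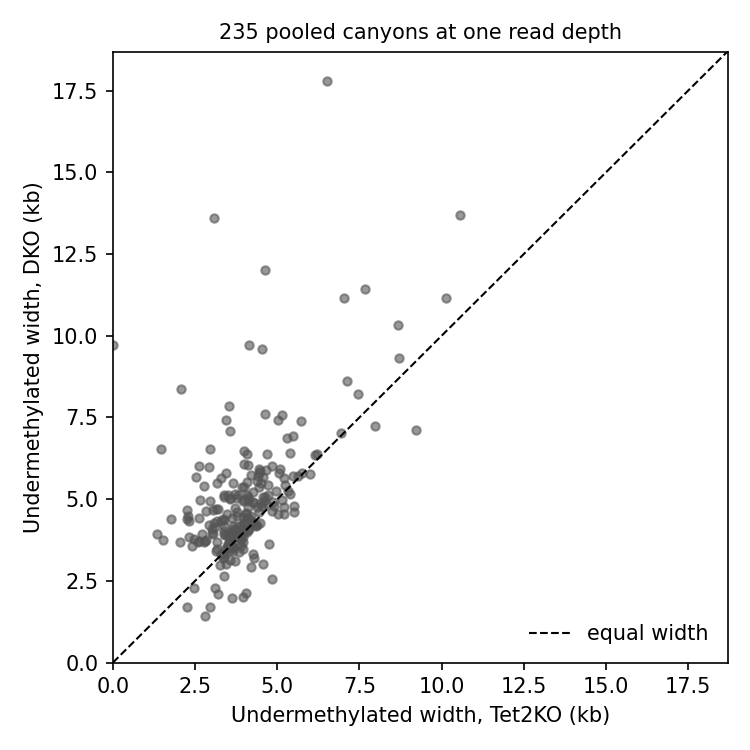
Undermethylated width of each of the 235 pooled canyons in the double knockout (vertical axis, kb) against the Tet2 knockout (horizontal axis, kb), at the same read depth. Each point is 1 canyon and the dashed line marks equal width; 179 points lie above the line and 56 below it, and 1 canyon not called in the Tet2 knockout is drawn at 0.

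The widest canyon covered Nkx2-3, a homeobox gene (mm9, chromosome 19, 43680788 to 43691607, 10820 bp). Its flanks were at 73.9% and 86.8% in the Tet2 knockout libraries (115 and 91 reads) and at 26.8% and 16.7% in the double knockout libraries (97 and 78 reads). The next 4 all lay on chromosome 11, outside every listed transcript. Among them, the canyon at 120091127 to 120099770 was 7660 bp wide in the Tet2 knockout and 11417 bp in the double knockout, and its flanks were at 43.8% and 4.06%. Its nearest listed genes were Ndufaf8, 129389 bp away, and Actg1, 107234 bp away, and unlisted genes may lie closer. The flanks of the canyon at 23973950 to 23984217 were at 48.8% and 10.1%, and those of the canyon at 18770087 to 18779279 at 35.1% and 7.88%. The canyon at 18909545 to 18919703 had flanks near 0 in both genotypes (2.37% and 2.14%). Of the 228 canyons with enough flanking reads, 92.5% had lower flanks in the double knockout. Examples over genes, chosen after their values were seen, were Hlx (69.4% to 15.8%), Smad7 (63.5% to 24.3%) and Smad3 (38.3% to 9.26%). Mycn (54.5% to 29.6%) and Sall3 (12.2% to 1.38%) were chosen in the same way. The flanks of the Spry2 canyon went from 80.4% to 70.7%, and those of the Alcam canyon rose from 39.7% to 47.3%. Whether canyons over developmental and signalling genes differ from other canyons was not tested.

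The Hox clusters, also chosen after their values were seen, had lower mean methylation in the double knockout. Hoxa (chromosome 6, 52105366 to 52210874) was at 29.8% ± 1.56 in the Tet2 knockout and 11.6% ± 0.167 in the double knockout (SD, n = 2 each). Hoxb was at 33.8% and 21.0%, Hoxc at 15.7% and 7.42%, and Hoxd at 22.5% and 11.9%. Of the 75 Hoxa tiles of 1000 bp with at least 20 reads in every library, edgeR's quasi-likelihood test called 23 lower; it called 12 of 108 in Hoxb, 4 of 71 in Hoxc, 6 of 67 in Hoxd, and none higher in any of the 4 clusters. Over all 705481 such tiles, 2.44% were called lower. The span listed for Hoxa3, which contains Hoxa4, held 15 of the 23 lower Hoxa tiles, of 28 tested. By number of lower tiles, Igf1r (21 of 202) and Maml3 (17 of 296) ranked highest among listed spans. That ranking favours long spans, which hold more tiles.

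Most of the single tiles called were lower in the double knockout, except in the set with at least 10 reads per site. Of 39381 tiles of 1000 bp with at least 3 well-covered CpG sites, 642 were lower and 19 higher (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05 and at least 20 points). An unadjusted p under 0.05 was reached by 4382 tiles, where chance gives 1969.05. The median level of the lower tiles was 88.5% in the Tet2 knockout and 23.6% in the double knockout. The number called, 661, depends on every library: it was 2 without Tet2 knockout replicate 1, 20 without Tet2 knockout replicate 2, 142 without double knockout replicate 1 and 164 without double knockout replicate 2, and limma on logit methylation called 1 tile. With at least 10 reads per site in every library, 6 of 1996 tiles were lower and 5 higher, so the split was not kept there. Of 705481 tiles with at least 20 reads in every library, a set added after the data were seen, 17233 were lower and 112 higher.

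The largest falls were nearly complete switches at 3 or 4 CpG sites each, and none lay in a listed transcript. A tile on chromosome 6 at 125032001 went from 100% in both Tet2 knockout libraries to 0% in both double knockout libraries (120 reads, edgeR adjusted p 3.86e-12). Its nearest listed transcripts were Cd4, 193774 bp away, and Gapdh, 78870 bp away. The others lay on chromosome 7 at 52490001 (-100 points), chromosome 3 at 89072001 (-96.7 points), chromosome 1 at 134188001 (-95.3 points), and chromosome 13 at 37528001 (-94.8 points). On chromosome 1 the nearest listed transcripts were Lemd1 (34042 bp away) and Klhdc8a (6203 bp). On chromosome 13 they were Ly86 (17096 bp) and Ssr1 (534270 bp). Only part of all transcripts is listed, so unlisted genes may lie closer or overlap these tiles. The largest rises lay on chromosome 5 at 72835001 (8.62% to 79.8%, adjusted p 0.00247) and 107244001 (1.02% to 57.8%), chromosome 10 at 99062001 (34.7% to 88.2%), X at 166436001 (5.18% to 57.9%, 1513 reads) and chromosome 15 at 100196001 (48.2% to 98.3%). The tile on X is from a chromosome whose depth relative to autosomes differed between the genotypes.

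In RNA, the neuronal tubulin gene Tubb3 and the endocytic gene Ehd3 were higher in the double knockout with the lowest adjusted p, and the immediate-early gene Ier2 and the mast cell protease gene Cma1 were among those that fell. Of 399 transcripts listed in all 4 libraries above 1 FPKM in at least 2, limma called 30 at a Benjamini-Hochberg adjusted p under 0.05, 15 higher and 15 lower in the double knockout. An unadjusted p under 0.05 was reached by 114, where chance gives 19.95. The FPKM of both genotypes were separate for 61.7% of transcripts, where chance gives 33.3%. After quantile normalization the call was 4 higher and 1 lower, and without a filter on low values limma called 0 of 2188 transcripts, with 236 at an unadjusted p under 0.05, where chance gives 109.4. Without Tet2 knockout replicate 1 the call was 137 transcripts, and without Tet2 knockout replicate 2 it was 72. Without double knockout replicate 1 the call was 26, of which 5 were higher. Of 2521 transcripts above 1 FPKM in any library, only 442 were listed in all 4, so most expressed genes were outside this test, among them every member of the stem cell and erythroid lists.

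Fold changes are on the log2(FPKM + 1) scale. Tubb3 was at 0.32 ± 0.0189 FPKM in the Tet2 knockout and 3.33 ± 0.113 in the double knockout (SD, n = 2 each), a log2 fold change of 1.72 ± 0.171 (SE; limma adjusted p 0.0144). Ehd3 went from 3.75 ± 0.138 to 11.3 ± 0.0358 FPKM, a log2 fold change of 1.37 ± 0.132 (limma adjusted p 0.0144). Tmem88 was listed at 0 in both Tet2 knockout libraries and at 1.52 and 1.32 FPKM in the double knockout. The chemokine receptor genes Ccr1 and Cx3cr1 rose by 1.14 and 0.83, and the neighbouring genes Frat1 and Frat2, which encode Wnt pathway regulators, by 0.81 and 0.75. Hmga2-ps1 (1.07), Ldhal6b (0.91), Serpine2 (0.83), Sowaha (0.81) and Them6 (0.60) rose as well. Ier2 went from 57.9 ± 3.01 to 27.4 ± 3.83 FPKM, a log2 fold change of -1.06 ± 0.124 (limma adjusted p 0.0193). Other falls were Tmem121 (-1.39), Perp (-1.36), Cma1 (-1.30), Cbr2 (-1.21), S100a5 (-1.11), Zfp987 (-1.04), Bok (-1.001), Lrg1 (-0.96), Apln (-0.90; on X, whose depth in the bisulfite libraries differed between the genotypes), Arl3 (-0.77) and Olfr856-ps1 (-0.75).

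Of the 4 gene lists with at least 3 tested members, none passed a directional test after adjustment. The neutrophil list (Lcn2, S100a8, Camp; median log2 fold change -0.79) had a camera p of 0.0405 over these genes with limma, 0.157 after adjustment and 0.319 with an estimated correlation. The macrophage list (Hmox1, C1qb, Cd5l) had an adjusted camera p of 0.157, the immediate-early list 0.157 and the myeloid list 0.740; with an estimated correlation or with fry's directional test no list passed. Fry's mixed test, which asks for changes in either direction, gave adjusted p-values of 0.00542 for the myeloid list, 0.0397 for the immediate-early list and 0.151 for the others. Adjusted over the list alone, 2 neutrophil genes, 1 macrophage gene and 2 immediate-early genes were lower, and 1 myeloid gene was higher and 1 lower. S100a8, a neutrophil gene, was at 759 and 851 FPKM in the Tet2 knockout and at 711 and 374 in the double knockout, and was not called. The neutrophil and macrophage lists were fixed as markers of contaminating cells. Whether the share of such cells differed between the libraries was not tested.

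A set added after the data were seen took transcripts listed in at least 3 libraries, and limma called 106 of its 839 transcripts, 45 higher and 61 lower. A transcript listed in 3 libraries has 1 library in one genotype, which limma assumes to vary like the others, so these calls have no replicate check in that genotype. Such values describe the libraries and do not show a difference between genotypes. Cldn13, expressed in erythroid cells, was at 2.73 FPKM in Tet2 knockout replicate 2 against 16.7 and 13.9 in the double knockout, and the interferon gene Isg15 at 9.93 and 12.0 FPKM in the Tet2 knockout against 36.9 in double knockout replicate 1. Hoxb5 was at 4.04 FPKM in Tet2 knockout replicate 2 against 0.985 and 1.40. C1qa, a macrophage gene, was at 29.99 FPKM in Tet2 knockout replicate 2 against 11.4 and 8.12 in the double knockout. C1qb, listed in all 4, was also highest in that library, at 11.2 FPKM in Tet2 knockout replicate 1 and 27.3 in replicate 2, against 10.7 and 9.87 in the double knockout. Gadd45g was at 2.55 and 3.06 FPKM against 8.63 in double knockout replicate 2. Its canyon was 4046 and 4470 bp wide in the Tet2 knockout libraries and 4004 and 5908 bp in the double knockout libraries, so any widening there rests on double knockout replicate 2.

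CMS summits of the genotypes overlapped in part. The autosomes held 77248 summits in the Tet2 knockout and 89049 in the double knockout. Within 1000 bp of a summit of the other list lay 30.9% (95% Wilson interval 30.6 to 31.3) of the Tet2 knockout summits and 27.4% (27.1 to 27.7) of the double knockout summits, where shuffled positions gave 7.08% and 6.24%. The lists differed at undermethylated regions: 52.7% of the 9031 regions held a double knockout summit, against 5.79% for shuffled positions, and 1.07% held a Tet2 knockout summit, against 5.07%. The highest-scoring shared summit lay on chromosome 18, at 90771597 in the Tet2 knockout (score 775) and at 90771594 in the double knockout (score 919), outside every listed transcript. Each list comes from 1 library, so these values have no replicate check.

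Bisulfite reads cannot tell 5-hydroxymethylcytosine from 5-methylcytosine, so the methylation around CMS summits is the sum of both. It was lower in the double knockout at every class of summit: 75.1% ± 1.22 against 65.2% ± 0.221 around shared Tet2 knockout summits, 79.6% ± 0.899 against 67.7% ± 0.156 around those of the Tet2 knockout alone, and 43.8% ± 1.41 against 33.7% ± 0.0547 around those of the double knockout alone (SD, n = 2 each). Random positions were at 80.9% and 73.5%. Lower tiles held a Tet2 knockout CMS summit more often than all tested tiles did (9.78% against 6.97%, Fisher's exact test across tiles, adjusted p 0.0209). They held a double knockout CMS summit less often (7.57% against 12.2%, Fisher's exact test, adjusted p 0.000603). In the added set of tiles they held such a summit more often (7.77% against 5.14%), so that direction depends on the tiles tested. Tiles that start near 0 cannot fall by the minimum difference. In the set tested first, 0 of 4025 tiles at 0 to 10% in the Tet2 knockout were called lower. Double knockout summits were frequent in undermethylated regions, and tiles were not matched for starting level. These tests therefore cannot tell whether lower tiles and CMS summits go together beyond their starting levels. Tiles are not independent replicates.

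H3K27me3 lists shared few positions, and their formats differ: the Tet2 knockout list holds intervals and the double knockout list 1 bp summits. Of 15685 autosomal Tet2 knockout intervals, 7.78% (95% Wilson interval 7.37 to 8.21) held a double knockout summit, and of 11438 double knockout summits 10.98% (10.4 to 11.6) lay in a Tet2 knockout interval; shuffled positions gave 0.217% and 0.293%. The highest-scoring shared Tet2 knockout interval lay on chromosome 4, 118219685 to 118221315, and held the second-highest shared double knockout summit at 118220578. A high-scoring shared double knockout summit lay in Smo, on chromosome 6 at 29698365. Methylation was 28.8% ± 1.39 and 21.2% ± 0.417 in intervals of the Tet2 knockout alone, 27.6% ± 3.11 and 19.9% ± 0.401 in shared intervals, and 65.9% ± 1.25 and 57.8% ± 0.198 around summits of the double knockout alone (SD, n = 2 each). Of 28 canyons with a Tet2 knockout H3K27me3 interval 22 were wider in the double knockout, against 157 of 207 others (Fisher's exact p 1).

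At genes, RNA changes were set beside methylation over the listed transcript spans, and beside marks over these spans and 1000 bp either side. Most spans had lower methylation in the double knockout, whatever their RNA did: 15 of 15 genes called higher, 11 of 13 called lower and 300 of 345 others. Chosen after their values were seen, the spans of Tmem88 (53.7% to 3.40%) and Hmga2-ps1 (64.3% to 18.4%), which rose in RNA, and of Tmem121 (59.7% to 32.4%), which fell, had large differences. Tubb3 and Sowaha, which rose, and Lrg1, which fell, carried H3K27me3 in both genotypes. The median span difference was -10.8 points for 15 higher genes, -7.75 points for 13 lower genes and -5.67 points for 345 others. None of 10 comparisons of marks between called and other genes passed Fisher's exact test after adjustment (lowest adjusted p 0.0783); the lowest unadjusted p was 0.00783. With genes called at an adjusted p under 0.1, 7 of 27 higher genes held a Tet2 knockout H3K27me3 interval against 19 of 306 others (adjusted p 0.0238), and 7 held a double knockout summit against 24 (adjusted p 0.0357). Genes are not independent replicates.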

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

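The tests of conversion, depth, donor sex and loss of Dnmt3a in this part were all chosen after the lower methylation had been seen.

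Signals on the sex chromosomes differed between the genotypes. Y entered no comparison of methylation or peaks, and X entered the tile and RNA tests but not the comparisons of peaks. The double knockout bisulfite libraries listed 12341 and 11386 CpG sites on Y, against 2701 and 2462 in the Tet2 knockout. Their depth on X relative to autosomes was 0.483 and 0.480, against 0.911 and 0.891. The double knockout CMS list had 1104 summits on unplaced Y sequence against 3, and 1265 on X against 4014. The H3K27me3 lists went the other way on X, with 944 summits in the double knockout against 109 intervals in the Tet2 knockout.

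The pattern weighed is the lower CpG methylation of the double knockout. A difference in bisulfite conversion is argued against by mitochondrial DNA, whose level was higher in the double knockout by 0.226 points rather than lower. For canyon numbers, a difference in depth is argued against by calls at the same depth: the double knockout library with fewer had 352, against 152 and 168 in the Tet2 knockout. The mean level was not computed at one depth. Double knockout depths (3.75 and 3.21 mean reads per site) lay between those of the Tet2 knockout (4.33 and 2.45). Donor sex cannot be told apart from genotype, since 0 genotypes held libraries with both kinds of X depth, and the bisulfite donors may have been female in the Tet2 knockout and male in the double knockout. Loss of Dnmt3a would give lower levels on all 19 autosomes, but these are part of the pattern itself and cannot tell it from donor sex. While donor sex stays open, loss of Dnmt3a remains a hypothesis.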

How the results depend on the processing

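The alternatives called added here were chosen after the data were seen; the others were fixed before. All methylation differences below kept their direction. The mean autosomal difference was -5.89 points over sites with at least 1 read, -7.27 over sites with at least 5, -8.03 over sites with at least 10. With summed reads it was -5.20 over sites with at least 5 reads (added), -3.19 over sites with at least 10 and -6.64 over sites of at most 100 reads (added); it ran from -5.37 to -4.92 with each replicate left out. The number of changed tiles was 1 with limma on logit methylation, 1 after centring too, 2590 with Fisher's exact test on pooled reads, 11 (6 lower, 5 higher) of 1996 with 10 reads per site, 14179 of 1561301 with 1 read per site, and 17345 of 705481 with at least 20 reads per tile (added). It ran from 2 to 164 with each replicate left out, where the lone library of a genotype is assumed to vary like the others. Flanks of undermethylated regions differed by -17.1 points with a 15% level, -13.1 with 5%, -15.2 with smoothing over 3 sites and -16.1 over 9, and by -16.2 to -15.0 with each replicate left out. Canyons numbered 375 with a 15% level, 96 with 5%, 1781 from 2000 bp and 52 from 5000 bp, and 195 to 274 with each replicate left out.

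Changed transcripts numbered 5 (4 higher, 1 lower) after quantile normalization, 0 (0 higher, 0 lower) of 2188 with limma without a filter (236 at an unadjusted p under 0.05, where chance gives 109.4), 8 (5 higher, 3 lower) with FPKM above 5, 14 (6 higher, 8 lower) with a log2 change of at least 1, 106 (45 higher, 61 lower) listed in at least 3 libraries (added), and 127 (56 higher, 71 lower) listed in each genotype (added). With each replicate left out they ran from 26 to 137 (5 to 47 higher, 16 to 90 lower). Of 299 values of 24 named genes, 204 kept their call, 95 kept their direction without passing and 0 reversed. These genes were picked for groups that do not overlap. Leaving out a replicate, a replicate block or another pseudocount therefore could not reverse them, and their kept direction is no sign of robustness. Of 28 values of 4 gene lists, 24 kept their side of the threshold, 3 were weaker and 1 stronger. With the replicate number as a block, 3 transcripts (3 higher, 0 lower) and 539 tiles were called. Same-numbered libraries deviated with a correlation of 0.0483 in RNA and -0.00221 in tiles. These values give no sign that the numbers pair the samples. They cannot exclude pairing: bisulfite replicates differed only about as much as the strands of a library.

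Shared CMS summits (Tet2 knockout and double knockout lists) were 27.2% and 23.9% in the upper part of each list by score, 28.5% and 29.01% with equal numbers of top summits, 19.03% and 16.5% within 250 bp (added), and 51.4% and 49.4% within 5000 bp (added). Shared H3K27me3 peaks were 16.1% and 18.97% within 1000 bp, 6.83% and 9.37% in the upper part by score, 9.20% and 9.49% with equal numbers, and 25.9% and 22.0% within 5000 bp (added). Methylation differences at CMS summits with sites of at least 10 reads were -7.34 (shared) and -14.2 (double knockout alone), with at least 1 read -7.64 (double knockout alone), and in the upper part by score -8.48 (shared), -12.8 (Tet2 knockout alone) and -8.49 (double knockout alone). At H3K27me3 peaks they were -10.3 (shared) and -11.9 (Tet2 knockout alone) with at least 10 reads, -6.46 (Tet2 knockout alone) and -6.51 (double knockout alone) with at least 1 read, and -6.47 (Tet2 knockout alone) in the upper part by score. Comparisons of marks at genes that passed numbered 2 with genes called under 0.1. The cause of these differences was not tested. Tests for RNA counts, an overlap of 50% of a peak and promoter windows were not run, since the files hold no RNA counts, 1 bp summits and no strand. Single tiles were hard to call in the simulations: falls of 20 points were recovered in 0.1% of tiles starting above 50% and in 9.2% of those above 85%. Other depths were not simulated.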

Other observations

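In this part the tests of CMS summits were set before their deciding values were seen, and the test of RNA against methylation of transcript spans was chosen after part of its result had been seen.

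The pattern weighed first is that 52.7% of undermethylated regions held a double knockout CMS summit and 1.07% a Tet2 knockout summit. Hydroxymethylated cytosines, which bisulfite reads count as methylated, stay open: within 500 bp of those summits the double knockout level was 0.328%, which differs by -0.483 points from regions without a summit, but the regions were chosen for low levels in these same libraries, so a low level was set in advance. Pull-down background at CpG-dense DNA may explain part of it, since among 4 equal classes of regions by CpG density the highest held a summit 1.63 times as often as the lowest. Such background stays open, because the share did not climb steadily (34.4%, 56.7%, 63.5% and 56.1% from the lowest class to the highest). Nor does it say why the Tet2 knockout library lacked such summits. Each genotype has 1 CMS library, so a difference between these preparations was not tested.

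The other hypothesis was that genes whose spans lost more methylation rose in RNA. Across 373 transcripts, Spearman's rho between log2 fold change and the methylation difference (double knockout minus Tet2 knockout) was 0.140 (permutation p 0.00659; Pearson's r 0.0326), so genes that lost more tended, weakly, to be lower in RNA. In the added set of 1142 transcripts rho was 0.103. This is the opposite of the hypothesis, although the median loss was larger for the 15 genes called higher (-10.8 points) than for the others (-5.67 points). Genes are not independent replicates.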
